A study of Escherichia coli with 8 samples.

How the data were processed

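The data are RNA sequencing libraries of Escherichia coli K12, 2 for each of 4 groups: total RNA at 37 °C, total RNA at 42 °C, new RNA at 37 °C and new RNA at 42 °C. Per the labels' protocols, cells grown in M9 medium with glucose and tryptone to an OD600 of about 0.3 were given 100 µM AzG and kept at either temperature for 10 minutes. RNA was then extracted, coupled to DBCO-biotin and, for new RNA, pulled down with streptavidin beads. Libraries were made with a directional kit from 3 µg of total RNA or 20 ng of new RNA, per the labels' protocols. The labels state neither a ribosomal RNA depletion nor the strand and multi-mapping settings of the counting, so antisense and overlapping genes and near-identical copies are uncertain.

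The authors deposited raw counts per annotated feature for 4497 features, and FPKM for 4470. Per the submitters' processing notes, CASAVA 2.19, Trim Galore 0.6.5, HISAT2 2.1.0, SAMtools 1.3, featureCounts 1.6.3, StringTie 2.1.4 and DESeq2 1.20.0 were used with the build ASM584v2; those notes as used here give no order. The authors also deposited a table of DESeq2 results, with mean signal over libraries, log2 fold changes with their standard errors, a Wald score, and raw and adjusted p-values, for heat in new RNA and in total RNA. Its header does not state the direction; its log2 fold changes correlated with those computed here as 42 °C minus 37 °C (r = 0.954 for new RNA and 0.9997 for total RNA). In that authors' deposited table, 77 genes were higher and 56 lower in new RNA, and 91 and 130 in total RNA, and it called 43 of the 43 and 138 of the 143 genes called here. Gene names come from the files, and 4429 features matched the reference gene table of the same build, which gave coordinates and lengths.

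Samples were grouped by the titles in the labels. Libraries held 4101823 to 5150967 counts (new RNA) or 8300720 to 9327900 (total RNA). Replicates differed by more than sampling noise in all 4 groups, with chi-square per degree of freedom of 25.8 and 19.3 in total RNA at 37 °C and 42 °C and 5.15 and 5.11 in new RNA, so none looked like a second copy of another library. This sets the spread against counting noise alone and does not show separate cultures. Correlations of log2 CPM between the libraries of a group were 0.945 and 0.950 in new RNA and 0.988 and 0.993 in total RNA.

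The main test was edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, on the deposited counts with TMM factors. filterByExpr kept 4153 features. All 8 libraries entered 1 model with a mean per group and 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. TMM factors were 0.378 to 0.429 in new RNA and 2.42 to 2.47 in total RNA, so fold changes between the fractions are relative to the median gene. The biological coefficient of variation was 0.128. The contrasts were 42 °C minus 37 °C in new RNA and in total RNA, the difference of these, and new minus total RNA at each temperature. CPM values are normalised by TMM, and a mean of CPM is given with its SD over 2 libraries. Gene set tests used limma 3.58.1 (camera, with a preset correlation of 0.01, and fry) on log2 CPM with a prior count of 2, over 34 lists of at least 4 tested members. The 35 lists held 759 genes, of which 757 were in the count table. p-values of lists were adjusted over the 34 lists of each contrast.

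Before the data were examined, the groups, tests, lists, alternatives and the rule for named genes were fixed. The rule named 14 heat and cold shock genes whatever their values, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 10 CPM and no overlap of the groups, up to 4 members per list described, and, for the interaction, the 6 smallest p-values in each direction. For new over total RNA the 8 highest and 8 lowest genes at 37 °C were named. The 3 highest of these without ribosomal and transfer RNA genes, and the lists of low-oxygen, nitrogen and acid resistance genes, were added after the data were seen. Where both libraries of a group held 0 counts, a bound was computed against a floor of 3 counts over the group. Intervals and floors cover counting error only.

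The alternatives were DESeq2 1.42.0, other scaling (RLE, upper-quartile, library totals, stable RNA removed), no filter or at least 10 CPM in 2 libraries, only the 4 libraries compared, a replicate block, removal of length trends by offsets, limma on log2(FPKM + 1) or log2(FPKM + 0.1), a minimum change of 1 on the log2 scale, and leaving out each library. A fold change from FPKM is on the log2(value + pseudocount) scale and understates low genes. No genome sequence was used here, so base content was not tested.

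The scripts were tested on simulated counts with the totals of the 8 libraries and 200 changed genes among 4153. Before changes were added, each pair of groups compared was given the same mean share of each gene. For heat in new RNA, 14.9% of 1.5-fold, 38.8% of 2-fold and 74.2% of 4-fold changes were recovered, with 8 false calls. For heat in total RNA these were 28.4%, 73.1% and 97.0%, also with 8 false calls. For new over total RNA at 37 °C, 28.4%, 59.7% and 87.9% were recovered, with 4 false calls. There the mean share of ribosomal RNA lay between those of the 2 fractions. The simulated new RNA libraries at 37 °C thus held more counts of other genes than the real ones. The recoveries and list values of this comparison may therefore overstate what the real depth allows. None of the 34 lists was called in simulated data without a list effect, where genes were drawn independently of each other. With the TCA cycle list shifted, camera with the preset correlation called it in all 4 comparisons simulated. With an estimated correlation its adjusted p was 0.0657 for heat in new RNA, 0.0453 for heat in total RNA, 0.168 for the interaction and 0.0310 for new over total RNA at 37 °C (camera, 4153 genes). That setting therefore missed a planted shift in 2 of 4, and a call lost there does not show an unchanged list. Because simulated genes were independent, these runs do not test either setting where genes of a list move together. A call with the preset correlation may rest on such genes.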

Results

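The series asked which transcripts Escherichia coli K12 makes during a mild heat shock. Cells at an OD600 of about 0.3 received 100 µM AzG, an azidonucleoside taken up into RNA as it is made, and stood for 10 minutes at either 37 °C or 42 °C. RNA that carried AzG was coupled to biotin and pulled down with streptavidin. That fraction is called new RNA here, and unselected RNA of the same treatments is called total RNA. The 4 groups, new and total RNA at each temperature, held 2 libraries each, 8 in all. Total RNA libraries held between 8300720 and 9327900 counts, and new RNA libraries between 4101823 and 5150967. Ribosomal RNA took 86.2% ± 1.19 (SD, n = 2) of the counts in new RNA at 37 °C and 85.0% ± 0.226 (SD, n = 2) at 42 °C. In total RNA it took 0.0263% ± 0.0118 (SD, n = 2) and 0.0276% ± 0.0172 (SD, n = 2). New RNA therefore left 622685 to 765518 counts per library for all other genes, with a median of 27 to 33 counts per tested gene, against 282 to 319 in total RNA. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which can be technical.

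The first comparison asked which genes changed in RNA made during the 10 minutes at 42 °C. In new RNA, 30 of 4153 genes rose and 13 fell (edgeR, adjusted p threshold of 0.05). The largest increase among named genes was in hypC, a maturation protein of hydrogenases, at position 2851864 to 2852136 of the chromosome (build ASM584v2), from 5.82 ± 0.206 to 29.2 ± 4.59 CPM (mean ± SD, n = 2 and 2). The gene nirB, of a nitrite reductase subunit, rose from 33.1 ± 4.59 to 84.8 ± 1.77 CPM (SD, n = 2 and 2), and narG, of a nitrate reductase subunit, by 1.19 ± 0.24 on the log2 scale (SE). The ammonium transporter gene amtB and the glutamine transporter gene glnP rose by 1.37 ± 0.25 and 1.16 ± 0.21 (log2, SE). The regulator genes adiY and appY rose by 1.88 ± 0.28 and 1.31 ± 0.21, and ymgG by 1.31 ± 0.21 (log2, SE).

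Among the genes that fell in new RNA, sdhC, a membrane subunit of succinate dehydrogenase at position 755177 to 755566, went from 50.7 ± 4.26 to 18.6 ± 0.178 CPM (SD, n = 2 and 2), a log2 fold change of -1.44 ± 0.27 (SE). The neighbouring genes nrdH, nrdI and nrdE, of a ribonucleotide reductase operon, had log2 fold changes of -1.26 ± 0.21, -1.07 ± 0.18 and -1.09 ± 0.19 (SE). Lower values were also found for fhuF, of iron release from siderophores, at -1.35 ± 0.23, the tryptophan synthase gene trpB at -1.28 ± 0.23, yebY at -1.12 ± 0.19, and proP, an osmolyte transporter, at -1.01 ± 0.13 (log2, SE). The adjusted p-values of these 16 genes lay between 0.00435 and 0.0339 (edgeR). The naming rule required both libraries at 42 °C to lie on the same side of both at 37 °C. Of the 16, 2 kept their calls without new RNA replicate 1 at 37 °C, 0 without replicate 2 at 37 °C, 0 without replicate 1 at 42 °C and 1 without replicate 2 at 42 °C. All called genes depended on these libraries: the counts of higher and lower genes were 4 and 1 without replicate 1 at 37 °C, 0 and 0 without replicate 2 at 37 °C, 0 and 1 without replicate 1 at 42 °C, and 0 and 2 without replicate 2 at 42 °C. Leaving out total RNA replicate 1 at 37 °C, replicate 1 at 42 °C or replicate 2 at 42 °C moved the lower count to 20, 21 and 20. The 16 named genes all kept the sign of their change in each fit without 1 library. DESeq2 gave 76 higher and 54 lower, upper-quartile scaling 23 and 16, and library totals alone 56 and 12. With replicate number as a block, 139 genes were higher and 76 lower. The call of narG was also lost with upper-quartile factors (adjusted p = 0.0528), with at least 10 CPM in 2 libraries (0.0517) and with only the 4 new RNA libraries (0.0590). With limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) over all genes above 0, 5, 4 and 5 of the 16 kept their calls, among them hypC, adiY, nirB and ymgG.

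The heat-shock chaperone genes had some of the largest log2 fold changes in new RNA, but none passed the main test. Values in new RNA were 1.84 ± 0.61 for clpB, 1.76 ± 0.54 for htpG, 1.69 ± 0.54 for groL, 1.54 ± 0.42 for groS, 1.04 ± 0.33 for dnaK and 0.95 ± 0.30 for grpE (log2, SE), with adjusted p-values from 0.217 to 0.309 (edgeR). The chaperonin gene groL, at position 4371025 to 4372671, had 781 ± 328 CPM at 37 °C and 2519 ± 819 at 42 °C (SD, n = 2 and 2). In all 4 groups the libraries numbered 2 held more groL than those numbered 1, by 1.57 to 1.84 times, and more clpB, by 1.49 to 1.98 times. This spread widens the test, so a missing call does not show that these genes stayed the same. DESeq2 called these 6 genes, with adjusted p-values from 0.000581 to 0.0273, and the authors' deposited table gave an adjusted p of 0.00183 for groL. With replicate number as a block, 6 of the 6 were called (edgeR), and whether a number marks a shared culture stays open. The protease genes lon and hslU and the cochaperone gene dnaJ had log2 fold changes of 0.59 ± 0.18, 0.64 ± 0.24 and 0.53 ± 0.15 (SE), without a call. The small heat-shock protein genes ibpA and ibpB had -0.61 ± 0.29 and -0.85 ± 0.59, and rpoH, which encodes the heat-shock sigma factor, -0.04 ± 0.10 (log2, SE), with no call. The cold-shock gene cspA had -0.33 ± 0.10 and rpoE, of the envelope stress sigma factor, -0.36 ± 0.18, also without a call.

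**Figure D1:**
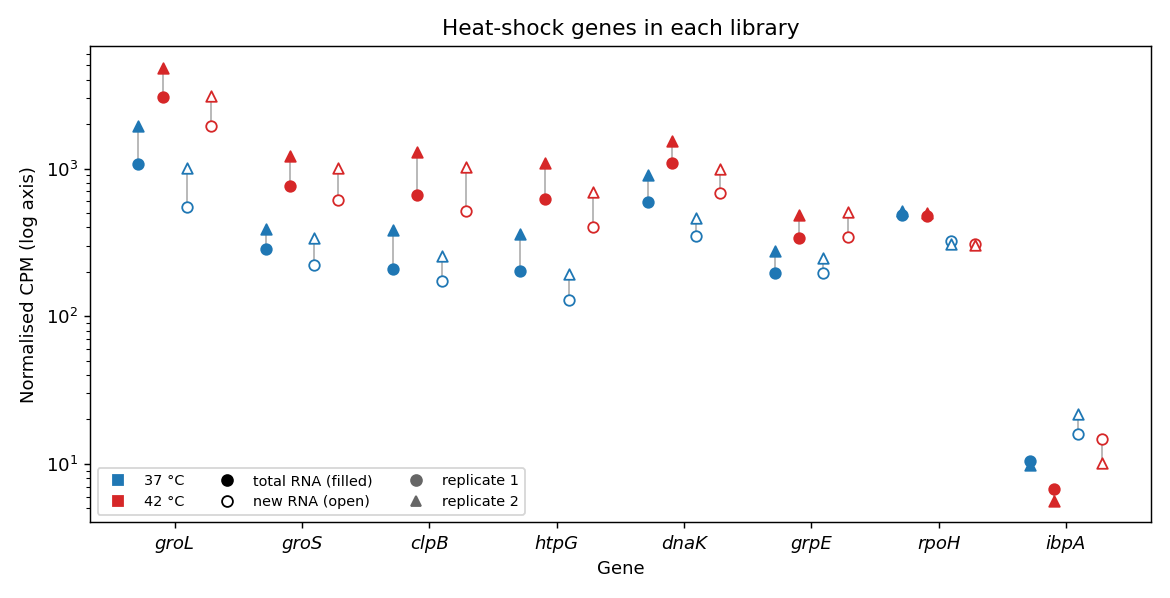
Normalised CPM (log axis) of 8 heat-shock genes in each of the 8 libraries; filled symbols are total RNA, open symbols new RNA, circles replicate 1 and triangles replicate 2, and a grey line joins the 2 libraries of a group. The libraries at 42 °C lie above those at 37 °C for groL, with group means of 2519 and 781 CPM in new RNA, while rpoH means are 306 and 315 CPM.

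Of the gene lists fixed before the data were examined, the 32 genes of the sigma32 regulon (chaperones and proteases of the heat-shock response) held 22 with a positive log2 fold change in new RNA. None was called over all genes and 3 were called when adjusted over the list alone, and the set test gave an adjusted p of 0.0653 (camera) and of 0.775 with an estimated correlation. As for groL and clpB, members such as htpG were higher in libraries numbered 2 in all 4 groups, by 1.51 to 1.77 times. Of 14 genes of the TCA cycle, 3 fell (sdhC, sdhA and acnB), 7 fell when adjusted over the list alone, and the median log2 fold change was -0.66. Its adjusted p was 0.000215 (camera) and 0.293 with an estimated correlation. The calls of sdhA and acnB were lost without any of the 4 new RNA libraries (adjusted p = 0.0622 to 0.128 and 0.101 to 0.140) and on log2(FPKM + 1) (0.0781 and 0.140). The 22 toxin-antitoxin genes had a median of 0.43, with 19 positive values and no called gene, also none when adjusted over the list alone. The set test gave an adjusted p of 0.00504 (camera), and adjusted p = 0.699 with an estimated correlation. That call was lost without new RNA replicate 2 at 37 °C (adjusted p = 0.1002) and without replicate 2 at 42 °C (0.305), and with fry (0.127). These were the 2 of 34 tested lists with a call in new RNA.

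Total RNA was compared between the temperatures in the same way. In total RNA, 69 genes rose and 74 fell at 42 °C. The regulator genes adiY and appY rose by 1.62 ± 0.16 and 1.51 ± 0.17 (log2, SE), appY from 26.1 ± 4.07 to 74.3 ± 13.9 CPM (SD, n = 2 and 2). The anaerobic C4-dicarboxylate transporter gene dcuC rose 2.64-fold, and on the log2 scale ydfZ rose by 1.39 ± 0.22 and tdcA, a regulator of threonine breakdown, by 1.32 ± 0.23 (log2, SE). The nitrogen transport genes glnP and amtB rose 2.47-fold and 2.33-fold, and ymgG by 1.29 ± 0.16 (log2, SE). Among genes that fell, phoH, at position 1084992 to 1086056, went from 24.2 ± 5.16 to 7.77 ± 1.33 CPM (SD, n = 2 and 2).

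Other genes that fell in total RNA were ydcI at -1.80 ± 0.32, the glucose dehydrogenase gene gcd at -1.54 ± 0.27, sdhC at -1.47 ± 0.21, efeO, of iron uptake, at -1.42 ± 0.29, yibF at -1.37 ± 0.25, fhuF at -1.32 ± 0.18 and nrdE at -1.27 ± 0.16 (log2, SE). The 16 named genes had adjusted p-values from 0.000722 to 0.0493 (edgeR). Here too the naming rule required both libraries at 42 °C to lie on the same side of both at 37 °C. The heat-shock genes clpB, htpG, groS, groL, dnaK and grpE had log2 fold changes of 1.72 ± 0.58, 1.61 ± 0.51, 1.55 ± 0.40, 1.39 ± 0.52, 0.82 ± 0.32 and 0.79 ± 0.28 (SE). None was called, with adjusted p-values from 0.149 to 0.298 (edgeR), while DESeq2 called clpB, htpG, groS and groL. With replicate number as a block, 6 of these 6 genes were called (edgeR). The level of ibpA was 0.72 lower on the log2 scale, at -0.72 ± 0.20 (SE), with adjusted p = 0.0663 (edgeR) and 0.0424 (DESeq2). Values were 0.40 ± 0.14 for dnaJ, 0.39 ± 0.18 for lon, 0.49 ± 0.23 for hslU, 0.07 ± 0.26 for ibpB, -0.05 ± 0.09 for rpoH, -0.11 ± 0.16 for rpoE and -0.14 ± 0.10 for cspA (log2, SE), without a call. Higher and lower counts were 187 and 135 without total RNA replicate 1 at 37 °C, 31 and 42 without replicate 2 at 37 °C, 18 and 22 without replicate 1 at 42 °C, and 29 and 24 without replicate 2 at 42 °C. DESeq2 gave 90 and 130, upper-quartile scaling 92 and 64, and a fit of only the 4 total RNA libraries 37 and 36. With replicate number as a block the counts were 195 and 216.

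Of the 16 genes named for total RNA, adiY, appY, glnP, ymgG, amtB, phoH, sdhC, fhuF and nrdE kept their calls without any single library. The calls of the other 7, dcuC, ydfZ, tdcA, ydcI, gcd, efeO and yibF, depended on single libraries: 12 of the 16 were kept without total RNA replicate 2 at 37 °C, 10 without replicate 1 and 13 without replicate 2 at 42 °C, 12 without either new RNA library at 37 °C and 13 without either at 42 °C. All 16 kept the sign of their change in each fit without 1 library. In the fit of only the 4 total RNA libraries the calls of dcuC (adjusted p = 0.163), gcd (0.135), efeO (0.0705) and sdhC (0.0602) were lost, and that of dcuC also with RLE factors (0.0506) and without a low-count filter (0.0516). The 3 tests on FPKM, in the order given for new RNA, kept 7, 0 and 6 of the 16.

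Of the 14 TCA cycle genes, 4 fell in total RNA (sdhC, sdhA, acnB and sdhB), 12 when adjusted over the list alone, and 13 had negative values. The median was -0.77, and the set test gave an adjusted p of 6.1e-10 (camera) and of 0.0683 with an estimated correlation. Of 26 iron uptake genes, 4 fell (fhuF, fhuA, fepD and fepB), 12 when adjusted over the list alone, with a median of -0.54. Its adjusted p was 4.0e-06 (camera), and adjusted p = 0.259 with an estimated correlation. Without total RNA replicate 1 or 2 at 42 °C the calls of sdhB (adjusted p = 0.0706 and 0.108), fepD (0.266 and 0.267) and fepB (0.147 and 0.403) were lost, and that of fhuA without replicate 2 at 42 °C (0.147) or at 37 °C (0.0548). Those of fepD and fepB were also lost without either new RNA library at 37 °C (0.0516 to 0.0601), that of fepD without total RNA replicate 1 at 37 °C (0.0575) and that of fepB without replicate 2 (0.116). With only the 4 total RNA libraries those of fepD (0.0612) and fepB (0.0602) were lost, and that of fepB with at least 10 CPM in 2 libraries (0.0595). The iron call was lost with fry (0.0728).

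Biosynthetic lists were lower in total RNA by the set test. Of 17 purine genes, purK, purB and purN fell (8 when adjusted over the list alone), with a median of -0.21. Of 16 tryptophan and aromatic genes, trpA, trpB and trpC fell (3 when adjusted over the list alone). The 8 histidine genes all had negative values, with no call over all genes and 3 when adjusted over the list alone. Of 12 fatty acid genes, accC fell (2 when adjusted over the list alone). Adjusted p-values were 4.6e-05, 0.000908, 0.00181 and 0.00362 in that order (camera), and with an estimated correlation the p-values were 0.130, 0.168, 0.332 and 0.209. The histidine call was lost without total RNA replicate 2 at 42 °C (adjusted p = 0.0768). Without total RNA replicate 1 or 2 at 42 °C the calls of purB (0.0861 and 0.140), purN (0.185 and 0.140), trpA (0.0946 and 0.154), trpB (0.0513 and 0.208), trpC (0.101 and 0.142) and accC (0.0513 and 0.140) were lost. That of purK was lost without replicate 1 at 42 °C (0.0815), and those of purB, purN and trpB without replicate 2 at 37 °C (0.0674, 0.0512 and 0.0711). With only the 4 total RNA libraries those of purN (0.0612) and trpB (0.0602) were lost, and that of purN with library totals alone (0.0606). The histidine call was lost with fry (0.204).

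Further lists with a call in total RNA held few called members. Aerobic respiration had cydB, a subunit of cytochrome bd oxidase, higher and cyoB, a subunit of cytochrome bo oxidase, lower among 30 genes (2 higher and 3 lower when adjusted over the list alone). Its adjusted p was 0.00483 (camera), 0.259 with an estimated correlation, and 0.119 without total RNA replicate 1 at 37 °C. The sigmaE list (27 genes, median -0.19), the aminoacyl-tRNA synthetases (23 genes, median -0.16) and RNA polymerase with Nus factors (8 genes, median -0.13) held no called gene over all genes, and 0, 0 and 2 when adjusted over the list alone. Their adjusted p-values were 0.00056, 0.00181 and 0.0403 (camera), and the p-values with an estimated correlation were 0.259, 0.332 and 0.259. The RNA polymerase call was lost without any single library other than total RNA replicate 1 at 42 °C, with adjusted p-values from 0.0547 to 0.103. Among lists with higher values, amino acid catabolism (20 genes, median 0.31) had tdcA and tdcB higher and dadA lower (2 and 2 when adjusted over the list alone), and toxin-antitoxin genes (median 0.18) had no called gene, also none when adjusted over the list alone. Their adjusted p-values were 0.0403 and 0.0248 (camera), and 0.259 and 0.435 with an estimated correlation. The amino acid catabolism call was lost without total RNA replicate 1 at either temperature (adjusted p = 0.141 and 0.0747) or without either new RNA library at 37 °C (0.0653 and 0.0652). The toxin-antitoxin call was lost without total RNA replicate 2 at 37 °C (0.0762) or at 42 °C (0.198). The call of cyoB was lost without any library other than total RNA replicate 1 at 37 °C (0.0541 to 0.376), and that of cydB without any other than total RNA replicate 2 at 42 °C (0.0560 to 0.432). The call of tdcA was lost without total RNA replicate 2 at 37 °C (0.0713), replicate 1 at 42 °C (0.101) or either new RNA library at 37 °C (0.0502 and 0.0506). That of tdcB was lost without the same 4 libraries (0.0593 to 0.196) or total RNA replicate 2 at 42 °C (0.387), and that of dadA without replicate 2 at 37 °C (0.0525) or either total RNA library at 42 °C (0.0946 and 0.121).

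Other processing also ended some of these calls. On log2(FPKM + 1) those of acnB, sdhB, fhuA, fepD, fepB, purK, purB, purN, trpA, trpB, trpC, accC, cydB, cyoB, tdcA, tdcB and dadA were lost, with adjusted p-values from 0.0512 to 0.404 (limma). That of cydB was lost with RLE factors (adjusted p = 0.0509), library totals alone (0.0546), no low-count filter (0.0513) and only the 4 total RNA libraries (0.123). That of cyoB was lost with upper-quartile factors (0.0858), library totals alone (0.0606), at least 10 CPM in 2 libraries (0.0781), only the 4 libraries (0.1001) and length offsets (0.0668), and that of tdcB with DESeq2 (0.0690) and only the 4 libraries (0.0569). With fry the calls of the sigmaE list (0.0728), aerobic respiration (0.0552), aminoacyl-tRNA synthetases (0.0951) and toxin-antitoxin genes (0.343) were lost. That of RNA polymerase was lost with length offsets (0.0664) and only the 4 libraries (0.0803), and that of toxin-antitoxin genes with length offsets (0.0938).

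**Figure D2:**
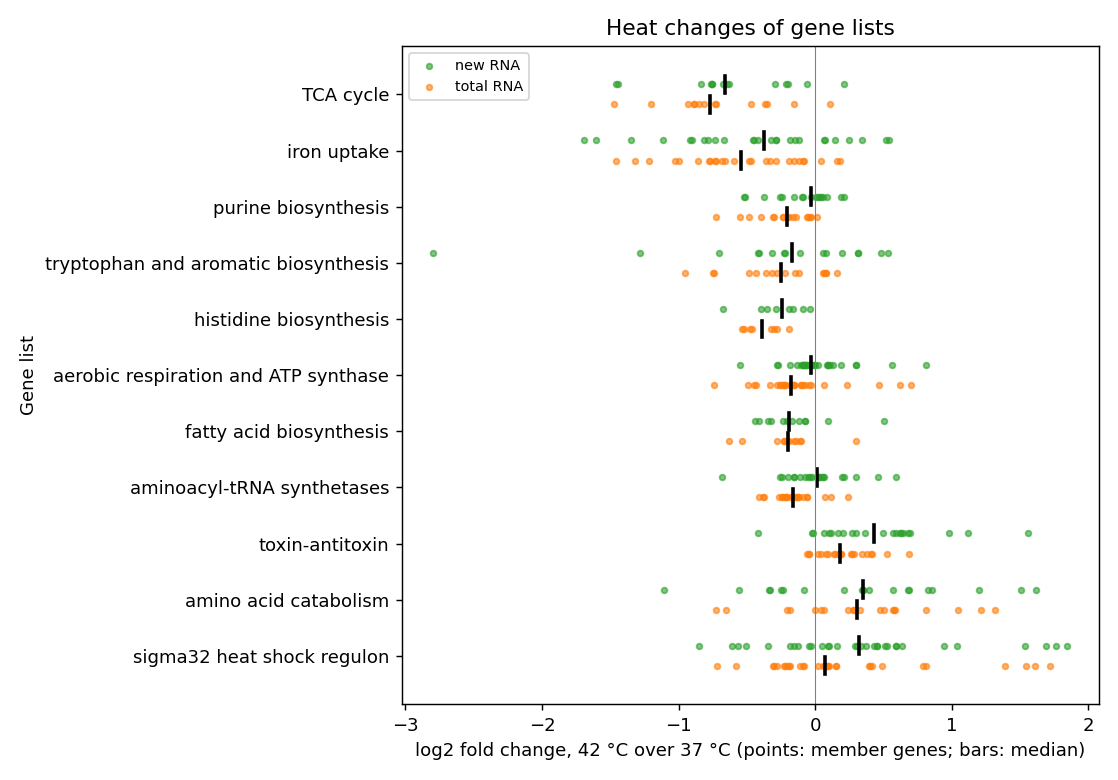
Log2 fold changes at 42 °C over 37 °C of the members of 11 gene lists, in new RNA (green) and total RNA (orange); points are genes and black bars list medians. TCA cycle medians are -0.66 in new RNA and -0.77 in total RNA.

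The next question was whether the heat response differed between new and total RNA. Genes called in new RNA were mostly called in total RNA as well: 21 genes, among them adiY, appY, amtB and glnP, were higher in both, and 11, among them sdhC, fhuF and nrdE, were lower in both. Independent lists of these lengths would share 0.498 and 0.232 genes. New and total RNA can come from the same cultures and genes of an operon move together, so that is not the value without a heat effect, and no test of the excess is given. Median ratios of the total RNA change to the new RNA change were 0.864 for genes called higher in new RNA and 0.938 for those called lower. For genes called in total RNA they were 0.911 and 1.22, and choosing genes in either fraction favours large values there. Across all 4153 genes, which are not independent replicates, Pearson's r of the changes was 0.276 and Spearman's rho 0.374. For the 613 genes with a mean of at least 100 CPM, a limit chosen after the data were seen, they were 0.868 and 0.741. Without new RNA replicate 1 at 37 °C the overlaps were 3 and 1, without replicate 2 at 37 °C 0 and 0, without replicate 1 at 42 °C 0 and 1, and without replicate 2 at 42 °C 0 and 2. Without total RNA replicate 1 at 37 °C the lower overlap was 18.

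No gene passed the test of the difference itself (the interaction of temperature and RNA fraction). edgeR found 0 higher and 0 lower, with a smallest adjusted p of 0.986 and 171 genes at an unadjusted p under 0.05, and DESeq2 also found 0. Without total RNA replicate 1 at 37 °C, 17 genes were lower. The smallest p-values belonged to pgaA (1.06 ± 0.26), gcvP (0.72 ± 0.18), ribC (0.70 ± 0.19), iadA (0.67 ± 0.20), yqjD (0.55 ± 0.17) and yidA (0.52 ± 0.16) in the direction of a higher value in new RNA (log2, SE). In the other direction they belonged to tatC (-0.57 ± 0.17), rnpB (-0.50 ± 0.16), amyA (-0.87 ± 0.29), yjbE (-0.86 ± 0.30), yjbD (-0.58 ± 0.22) and rstA (-0.59 ± 0.23). Among the heat-shock genes the difference ranged from -0.92 ± 0.65 for ibpB to 0.30 ± 0.73 for groL (log2, SE). In simulated data the test recovered 14.9% of 2-fold and 71.2% of 4-fold differences, so smaller differences were mostly not detectable at this depth. The 4 abundant stable noncoding RNAs, ssrA, ssrS, rnpB and ffs, had a median difference of -0.44 and none was called, 1 when adjusted over the list alone. Their set test gave an adjusted p of 0.0381 (camera), and adjusted p = 0.799 with an estimated correlation. That call was lost without total RNA replicate 1 at 37 °C (0.0547), new RNA replicate 1 or 2 at 37 °C (0.288 and 0.0643) or new RNA replicate 2 at 42 °C (0.549).

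**Figure D3:**
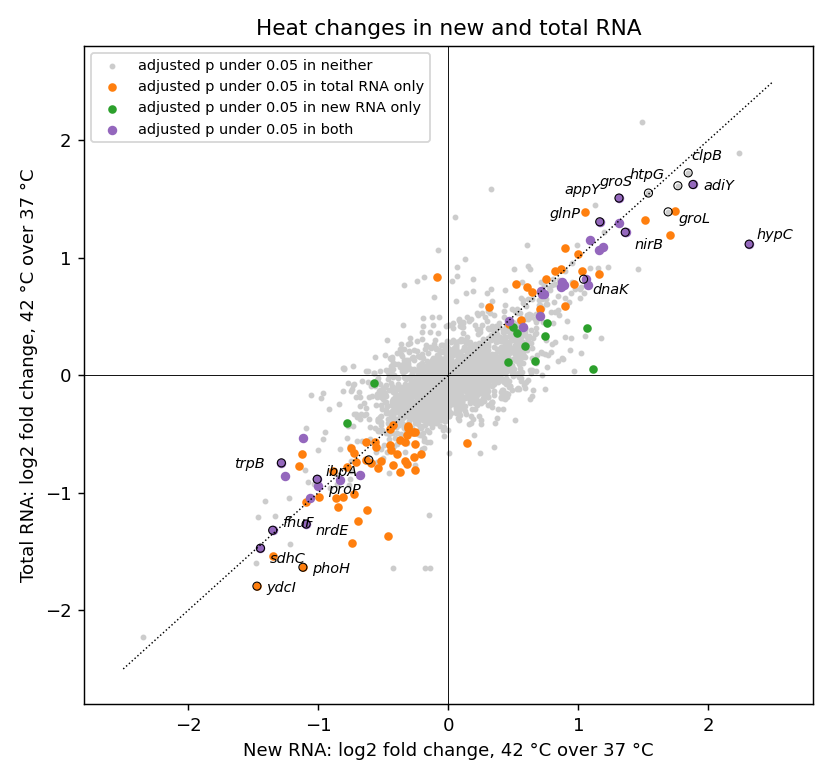
Log2 fold changes at 42 °C over 37 °C in new RNA (horizontal axis) and total RNA (vertical axis) for genes with a mean of at least 10 CPM; colours mark the fraction in which a gene was called, black circles mark named genes, and the dotted line is equality. Of the genes called in both, adiY (1.88 and 1.62) and sdhC (-1.44 and -1.47) lie near the line and hypC (2.31 and 1.11) farther from it.

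The last comparison set new against total RNA at the same temperature. It is a comparison of compositions: no pull-down without AzG was analysed here, so capture of unlabelled RNA is not subtracted, and the labels do not say whether ribosomal RNA was depleted from either kind of library. Ribosomal RNA took 84.8 to 87.0% of counts in new RNA libraries and 0.0154 to 0.0398% in total RNA libraries. The ribosomal RNA ratios below can therefore reflect a depletion of the total RNA libraries, and they are not read as enrichment by the pull-down. All 20 tested ribosomal RNA genes were higher in new RNA at 37 °C. The 23S gene rrlG rose from 10.7 ± 2.25 to 622420 ± 31869 CPM (SD, n = 2 and 2), a log2 fold change of 15.83 ± 0.29, and rrlD and rrsH had 15.44 ± 0.34 and 15.35 ± 0.47 (SE). The genes rrsD, rrsG, rrlA and rrsC had log2 fold changes between 14.45 and 14.77, and the 5S gene rrfF, with no count in total RNA at 37 °C, was at least 2011-fold higher against a floor of 3 counts over the group. At 42 °C, rrlG had 16.05 ± 0.29 and rrlD 15.28 ± 0.33 (log2, SE). Ribosomal RNA copies are near identical, so the split between copies is uncertain, as it is for tufA and tufB and for repeated transfer RNA genes.

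Of 79 transfer RNA genes, 20 were higher in new RNA and 1 lower at 37 °C. Higher genes lay mostly in or within 1 kb of the 7 ribosomal RNA operons: 11 of 14 such genes were called, with a median log2 fold change of 3.69, against 9 of 65 others, with a median of 0.42 (Fisher's exact test, two-sided, p = 4.6e-06). The 14 genes share 7 operons and are not independent, so this p-value overstates the evidence. Reads of the ribosomal precursor are not told apart from those of the tRNA there. A depletion of ribosomal RNA from the total RNA libraries could also remove such precursor reads. This contrast is therefore not read as enrichment by the pull-down either. The transfer RNA list had an adjusted p of 4.5e-07 (camera), 0.262 with an estimated correlation and 0.135 with length offsets. Among stable noncoding RNAs, ssrS (6S RNA) rose by 3.17 ± 0.14 and ffs (the signal recognition particle RNA) by 2.96 ± 0.49, while ssrA (tmRNA) had 0.57 ± 0.11 and rnpB -0.38 ± 0.12 (log2, SE). At 42 °C ssrS had 2.83 ± 0.13, ffs 2.24 ± 0.47 and rnpB -0.88 ± 0.12, all called, and ssrA 0.20 ± 0.11 (log2, SE) with adjusted p = 0.276 (edgeR). The sign for ssrA at 37 °C holds only where ribosomal RNA does not set the scale: with library totals alone it was -2.04, and that scaling also put the call of ffs at an adjusted p of 0.460. The call of ssrA was lost without new RNA replicate 1 at 37 °C (adjusted p = 0.0592), and the call of rnpB was lost without any single library, with adjusted p-values from 0.0736 to 0.359. That of rnpB was also lost with RLE factors (0.0627), upper-quartile factors (0.0620), at least 10 CPM in 2 libraries (0.170) and only the 4 libraries compared (0.164). On FPKM those of ffs (0.361 to 0.372) and ssrS (0.0554 to 0.0671) were lost, and at 42 °C that of ssrS with library totals alone (0.0721).

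Among other genes, chosen after their values were seen, deoB and deoD, which encode phosphopentomutase and purine nucleoside phosphorylase of nucleoside breakdown, stood out. At 37 °C deoB, at position 4619603 to 4620826, had 148 ± 1.46 CPM in total RNA and 3729 ± 781 in new RNA (SD, n = 2 and 2), a log2 fold change of 4.65 ± 0.22 (SE). At 42 °C its log2 fold change was 4.93 ± 0.22, and that of deoD was 3.26 ± 0.16 at 37 °C and 3.31 ± 0.16 at 42 °C (SE). The upstream genes of the operon, deoC and deoA, had -0.03 ± 0.13 and -0.53 ± 0.17 at 37 °C (SE), without a call. On FPKM the call of deoD was lost (adjusted p = 0.214 to 0.229, limma).

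Most listed genes for the machinery of growth were lower in new than in total RNA. Abundant protein genes of any kind were also lower at 37 °C. The median log2 fold change was -0.52 in 220 genes with a log2 CPM from 8 to 10 in total RNA, and -0.72 in 75 genes above 10. The lists and their set tests were not set against other genes of like abundance, so a property of these functions was not shown. Of 54 ribosomal protein genes, 41 were lower and 2 higher at 37 °C (45 and 5 when adjusted over the list alone), with a median of -0.82, for example rpsG at -1.25 ± 0.10, rpsJ at -1.27 ± 0.14 and rplK at -1.22 ± 0.13 (log2, SE). Of 14 glycolysis genes 13 were lower (14 when adjusted over the list alone), led by the enolase gene eno, which went from 3135 ± 365 CPM in total to 1118 ± 129 in new RNA (SD, n = 2 and 2), a log2 fold change of -1.49 ± 0.11 (SE). Of 23 aminoacyl-tRNA synthetase genes 18 were lower (19 when adjusted over the list alone), of 12 translation factor genes 9 (10), and of 8 RNA polymerase and Nus factor genes 7 (8). The other named genes were rimM (-1.42 ± 0.11), trmD (-1.40 ± 0.10), waaZ (-1.26 ± 0.20) and priB, which was 2.47 times lower. All 8 lowest genes had values between -1.59 and -1.20 at 42 °C.

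Set tests called 3 lists higher and 11 lower at 37 °C, and 3 and 7 at 42 °C (camera). The remaining lists lower at 37 °C were the sigmaE list (12 of 27 genes lower, 18 when adjusted over the list alone), fatty acid (7 of 12, 8), purine (9 of 17, 10), aerobic respiration (11 of 30, 14), sigma32 (5 of 32, 8) and outer membrane proteins (6 of 14, 8). The last of these had 1 higher gene, lpp at 1.21 ± 0.16 (log2, SE), which was -1.39 with library totals alone. The sigma32 call was lost without total RNA replicate 2 or new RNA replicate 1 at 37 °C (adjusted p = 0.104 and 0.123), that of outer membrane proteins without new RNA replicate 2 at 37 °C (0.0723), and that of toxin-antitoxin genes, higher at 42 °C, without new RNA replicate 2 at 42 °C (0.135). The sigma32 call was also lost with fry (0.0811), that of toxin-antitoxin genes at 42 °C with fry (0.0601) and length offsets (0.0555), and that of transfer RNA at 42 °C with length offsets (0.283). None of these calls held with an estimated correlation, where the smallest adjusted p was 0.196 at 37 °C and 0.263 at 42 °C. Counts of called genes were 214 higher and 413 lower at 37 °C and 218 and 311 at 42 °C, of which 131 and 262 were shared between the temperatures, against 11.2 and 30.9 for independent lists, with the same limit (edgeR). Without new RNA replicate 1 or 2 at 37 °C, the counts at 37 °C were 129 and 270, or 113 and 237. At 42 °C they were 106 and 149 or 116 and 180 without total RNA replicate 1 or 2, and 144 and 205 or 115 and 182 without new RNA replicate 1 or 2. Scaling sets the split: with library totals alone, where ribosomal RNA shifted the median gene to -2.60 and -2.52, 29 genes were higher and 3929 lower at 37 °C, and 27 and 4011 at 42 °C, so all values above are relative to the median gene.

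**Figure D4:**
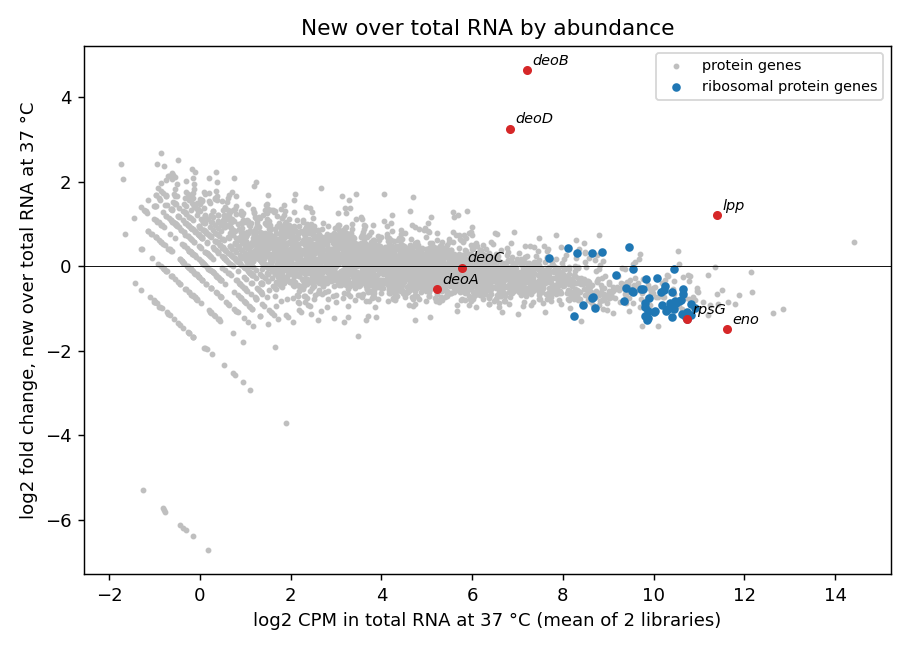
Log2 fold change of new over total RNA at 37 °C (vertical axis) against log2 CPM in total RNA at 37 °C (horizontal axis) for protein genes; blue points are ribosomal protein genes and red points genes named in the plot. The gene deoB lies at 4.65 and eno at -1.49.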

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

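The tests of this part were fixed before the data were examined, apart from the choice to describe single members. The 4 abundant stable noncoding RNAs, ssrA, ssrS, rnpB and ffs, were singled out because the test of the difference between the heat responses of new and total RNA passed for them as a list. The adjusted p was 0.0381 (camera), the median difference was -0.44 on the log2 scale, and 0 of the 4 members had a positive value: rnpB -0.50, ssrA -0.37, ssrS -0.34 and ffs -0.72. None of the 4 was called by edgeR or DESeq2 over all genes, and 171 of all genes had an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.799, with fry 0.273 and with length offsets 0.0765, and it was 0.0547 without total RNA replicate 1 at 37 °C, 0.288 and 0.0643 without new RNA replicate 1 or 2 at 37 °C, and 0.549 without new RNA replicate 2 at 42 °C.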

How the results depend on the processing

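The alternatives were fixed before the data were examined, except the limit of 100 CPM, the added lists and the 3 added genes. Below stand the values that moved past a limit. For a count the limit was 1.5 times, and for other values it was their SD over the fits without 1 library. The cause was not tested except where fewer libraries or a stricter limit make it plain. With DESeq2 there were 76 higher genes for heat in new RNA, 54 lower genes for heat in new RNA and 130 lower genes for heat in total RNA. The fit with DESeq2 gave overlap of higher genes 45, median ratio for genes called higher in new RNA 0.805, overlap of lower genes 37 and Spearman rho 0.324. With library totals alone there were 56 higher genes for heat in new RNA, 29 higher genes for new over total RNA at 37 °C, 3929 lower genes for new over total RNA at 37 °C, 27 higher genes for new over total RNA at 42 °C and 4011 lower genes for new over total RNA at 42 °C. The fit with library totals alone gave median ratio for genes called higher in new RNA 0.708 and median ratio for genes called lower in total RNA 1.36. With log2(FPKM + 1) there were 13 higher genes for heat in new RNA, 0 lower genes for heat in new RNA, 10 higher genes for heat in total RNA, 8 lower genes for heat in total RNA, 27 higher genes for new over total RNA at 37 °C, 3993 lower genes for new over total RNA at 37 °C, 27 higher genes for new over total RNA at 42 °C and 4013 lower genes for new over total RNA at 42 °C. The fit with log2(FPKM + 1) gave overlap of higher genes 7, median ratio for genes called higher in new RNA 0.742, overlap of lower genes 0, median ratio for genes called lower in total RNA 1.43 and Pearson r 0.465. With log2(FPKM + 0.1) there were 13 higher genes for heat in new RNA, 1 lower gene for heat in new RNA, 0 higher genes for heat in total RNA, 0 lower genes for heat in total RNA, 27 higher genes for new over total RNA at 37 °C, 3904 lower genes for new over total RNA at 37 °C, 27 higher genes for new over total RNA at 42 °C and 3932 lower genes for new over total RNA at 42 °C. The fit with log2(FPKM + 0.1) gave overlap of higher genes 0, median ratio for genes called higher in new RNA 0.707, overlap of lower genes 0 and median ratio for genes called lower in new RNA 0.250. With log2(FPKM + 1) over all genes above 0 there were 12 higher genes for heat in new RNA, 0 lower genes for heat in new RNA, 10 higher genes for heat in total RNA, 7 lower genes for heat in total RNA, 29 higher genes for new over total RNA at 37 °C, 4095 lower genes for new over total RNA at 37 °C, 29 higher genes for new over total RNA at 42 °C and 4126 lower genes for new over total RNA at 42 °C. The fit with log2(FPKM + 1) over all genes above 0 gave overlap of higher genes 7, median ratio for genes called higher in new RNA 0.747, overlap of lower genes 0, median ratio for genes called lower in total RNA 1.38, r 0.424 and rho 0.341. With a log2 change of at least 1 there were 14 higher genes for heat in new RNA, 35 higher genes for heat in total RNA, 24 lower genes for heat in total RNA, 117 higher genes for new over total RNA at 37 °C, 39 lower genes for new over total RNA at 37 °C, 108 higher genes for new over total RNA at 42 °C and 29 lower genes for new over total RNA at 42 °C. The fit with a log2 change of at least 1 gave overlap of higher genes 10 and overlap of lower genes 4. With only the 4 libraries compared there were 27 lower genes for heat in new RNA, 37 higher genes for heat in total RNA and 36 lower genes for heat in total RNA. The fit with only the 4 libraries compared gave r 0.643 and rho 0.560. With only the 4 libraries compared the called lists were 2 higher for heat in new RNA. With stable RNA removed there were 123 lower genes for heat in total RNA. With stable RNA removed the called lists were 0 lower for the interaction, 0 higher for new over total RNA at 37 °C and 1 higher for new over total RNA at 42 °C. With upper-quartile factors the values were median ratio for genes called higher in new RNA 0.943 and median ratio for genes called lower in total RNA 1.105. With at least 10 CPM in 2 libraries the values were median ratio for genes called higher in new RNA 0.935, r 0.641 and rho 0.559. Without a low-count filter the values were r 0.168 and rho 0.324. With an estimated correlation the called lists were 0 higher for heat in new RNA, 0 lower for heat in new RNA, 0 higher for heat in total RNA, 0 lower for heat in total RNA, 0 lower for the interaction, 0 higher for new over total RNA at 37 °C, 0 lower for new over total RNA at 37 °C, 0 higher for new over total RNA at 42 °C and 0 lower for new over total RNA at 42 °C. With fry the called lists were 4 lower for heat in new RNA, 1 higher for heat in total RNA, 6 lower for heat in total RNA, 0 lower for the interaction and 14 lower for new over total RNA at 42 °C. With length offsets the called lists were 0 lower for the interaction and 1 higher for new over total RNA at 42 °C. With library totals alone the median gene lay at 0.11 for heat in new RNA and 0.12 for the interaction. In the main fit it lay at 0.0056 and 0.0445. Library totals alone and the 3 FPKM fits reversed ssrA to -2.04, -2.07, -2.07 and -2.07 and lpp to -1.39, -1.58, -1.58 and -1.58 at 37 °C.

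Replicate numbers were not treated as pairs, because no label ties a number to a shared culture and each comparison holds only 2 numbers. This choice stays open: the protocol says that bacteria given AzG were separated into 2 groups for the 2 temperatures, and the calls with a block had been seen when it was made. Libraries of a number deviated together over 1446 genes, with r from 0.199 to 0.497 (0.202 for heat in new RNA and 0.389 in total RNA), and from 0.176 to 0.483 without the sigma32 list. Over all genes r was as low as 0.0319. With 2 libraries per group the 2 numbers mirror each other, so the 12 library pairs hold 6 distinct values, all above 0. With the block, 6 of the 6 chaperone genes clpB, htpG, groL, groS, dnaK and grpE were called in new RNA and 6 of 6 in total RNA, against 0 and 0 without it (edgeR). In simulated counts of 4153 genes, 100 genes with a mean over 100 CPM were given a 2-fold heat change and a 2-fold shift between numbers. In new RNA 0 of the 100 were recovered without the block and 98 with it, and in total RNA 0 and 100. The block gave 11 and 15 false calls, a larger share than the 0.05 aimed at. The planted shift is the term that the block fits, so this gain was built in. It does not show that the real numbers mark shared cultures. With a replicate block there were 139 higher genes for heat in new RNA, 76 lower genes for heat in new RNA, 195 higher genes for heat in total RNA and 216 lower genes for heat in total RNA. The fit with a replicate block gave overlap of higher genes 94, median ratio for genes called higher in new RNA 0.739 and overlap of lower genes 59. With a replicate block the called lists were 4 higher for heat in new RNA, 2 lower for heat in new RNA, 4 higher for heat in total RNA and 0 lower for the interaction. With a block per fraction there were 110 higher genes for heat in new RNA, 60 lower genes for heat in new RNA, 162 higher genes for heat in total RNA and 168 lower genes for heat in total RNA. The fit with a block per fraction gave overlap of higher genes 76, median ratio for genes called higher in new RNA 0.776 and overlap of lower genes 49. With a block and length offsets there were 132 higher genes for heat in new RNA, 94 lower genes for heat in new RNA, 223 higher genes for heat in total RNA and 207 lower genes for heat in total RNA. The fit with a block and length offsets gave overlap of higher genes 99, overlap of lower genes 70 and median ratio for genes called lower in total RNA 1.10. The block kept 43 of the 43 genes called for heat in new RNA, 143 of 143 in total RNA, 624 of 627 for new over total RNA at 37 °C and 526 of 529 at 42 °C.

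Leaving out each library gave these ranges of counts: higher genes for heat in new RNA 0 to 41, lower genes for heat in new RNA 0 to 21, higher genes for heat in total RNA 18 to 187, lower genes for heat in total RNA 22 to 135 and higher genes for the interaction 0 to 0. Others were lower genes for the interaction 0 to 17, higher genes for new over total RNA at 37 °C 113 to 245, lower genes for new over total RNA at 37 °C 237 to 406, higher genes for new over total RNA at 42 °C 106 to 242 and lower genes for new over total RNA at 42 °C 149 to 336. For the comparison of the responses the ranges were overlap of higher genes 0 to 29, median ratio for genes called higher in new RNA 0.8003 to 0.925, median ratio for genes called higher in total RNA 0.903 to 1.305 and overlap of lower genes 0 to 18, and median ratio for genes called lower in new RNA 0.460 to 1.06, median ratio for genes called lower in total RNA 1.07 to 1.42, r 0.0913 to 0.284 and rho 0.291 to 0.379. Ranges of called lists were higher for heat in new RNA 0 to 3, lower for heat in new RNA 1 to 2, higher for heat in total RNA 1 to 4, lower for heat in total RNA 8 to 16 and higher for the interaction 0 to 4, and lower for the interaction 0 to 3, higher for new over total RNA at 37 °C 3 to 3, lower for new over total RNA at 37 °C 10 to 12, higher for new over total RNA at 42 °C 2 to 4 and lower for new over total RNA at 42 °C 7 to 8. Over all alternatives and named genes, for heat in new RNA 722 values kept their side of the threshold and 114 calls were lost, with 44 calls gained, and for heat in total RNA 1492 values kept their side of the threshold and 202 calls were lost, with 97 gained. For new over total RNA, 1588 values kept their side of the threshold and 65 calls were lost at 37 °C and 443 values kept their side of the threshold and 4 calls were lost at 42 °C. Where a group is left with 1 library, that library is assumed to vary like the others. Offsets for base content and the alternative with 1 gene per operon were not run. In simulated data 38.8% of 2-fold changes were recovered for heat in new RNA, and 73.1% in total RNA, so the lower depth of new RNA limits its counts.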

Other observations

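The lists, limits and tests of this part were chosen after the results were seen, except the tests of length offsets, of scaling and of even background. The low-oxygen list on which the length and scaling tests were run was itself chosen afterwards. The TCA cycle list was added to the scaling test after its value had been seen. Of 65 genes of metabolism at low oxygen, in a list written after their values were seen, 8 were called higher and 0 lower at 42 °C in new RNA, and 18 and 0 in total RNA (edgeR). In new RNA the higher count was 2 without new RNA replicate 1 at 37 °C and 0 without each of the other 3 new RNA libraries, 13 without either total RNA library at 37 °C and 14 without either at 42 °C. In total RNA it was 33, with 1 lower, without total RNA replicate 1 at 37 °C, 8 without replicate 2 at 37 °C and 5 without replicate 1 at 42 °C. Most members had no call, and in new RNA narJ, glpB and arcA had -0.95 ± 0.73, -1.53 ± 1.08 and -0.38 ± 0.16 (log2, SE). The medians were 0.76 and 0.73 on the log2 scale, with 56 and 61 positive values. The called members included adhE (alcohol dehydrogenase, 0.89 ± 0.10 and 0.77 ± 0.10), narG (1.19 ± 0.24 and 1.09 ± 0.16) and nirB (1.36 ± 0.17 and 1.22 ± 0.13) in new and total RNA (log2, SE), and 9 of the 65 are also in the lists fixed before. Of 8 genes of nitrogen limitation, 4 were called in new RNA (amtB, glnQ, glnP and glnA) and 6 in total RNA. The 4 became 1 without new RNA replicate 1 at 37 °C and 0 without each of the other 3 new RNA libraries. Their medians were 1.09 and 1.03, and glnA, of glutamine synthetase, had 0.72 ± 0.12 and 0.69 ± 0.12 (log2, SE). Of 12 acid resistance genes, 0 were called in either fraction (edgeR), with medians of 0.59 and 0.27.

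Libraries numbered 2 differed from those numbered 1 in the same direction in all 4 groups for some genes. Of 613 genes with a mean of at least 100 CPM, 10 were over 1.3 times higher in replicate 2 in all 4 groups: clpB, hdeB, mdtF, groL, htpG, hdeA, gadE, hdeD, groS and dnaK. The genes ompF, gatY and aspA were lower by as much. In 203 genes (33.1%) the difference had the same side in all 4 groups, where 4 independent groups would give 12.5%. New and total RNA can come from the same cultures and genes of an operon move together, so the excess over 12.5% was not tested. The 21 genes of the prophage e14 had 0 of 53094293 counts, which allows up to 0.0565 per 1e6 counts in all libraries together, and 26 of 4497 features had no count in any library.

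For the low-oxygen genes, length offsets moved other genes by at most 0.147 (log2) and left the median in total RNA at 0.73, which argues against a length trend as the whole cause. The lowest median over 5 other scalings was 0.71, but these put the median gene only between -0.012 and 0.044. They could therefore not lower the list far and decide nothing. A scaling moves all genes of a library alike, and the TCA cycle list stood at -0.77. This argues against a scaling as the whole cause of both. Less oxygen in the cultures at 42 °C may be a cause, tested by lower cytochrome bo and higher cytochrome bd oxidase genes, whose medians were -0.0642 and 0.69 in new RNA and -0.26 and 0.55 in total RNA. The bo median of -0.0642 is near 0, and its limit was moved from 0 to -0.2 after that value had been seen, so it decides nothing. The bd genes cydA and cydB are themselves members of the low-oxygen list, so the bd part is no independent test of less oxygen. Growth rate and temperature itself were not told apart from less oxygen.

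For deoB and deoD, more new transcription of the whole operon is argued against by deoC and deoA, of which the higher had -0.0315 where deoD had 3.26 (log2, new over total RNA at 37 °C). The deposited FPKM gave deoB 4.40 above the median gene, but they come from the same reads, so reads given to the wrong gene or strand stay open. Nucleic acid added with the pull-down may be a source: the excess of deoB was 1.46 times as large at 42 °C as at 37 °C, and a library without AzG, not analysed here, would be needed to decide. No biological explanation was tested.

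Across 3871 protein genes, the change from total to new RNA at 37 °C was lower at higher abundance in total RNA, with a rank correlation of -0.474 at 37 °C and -0.292 at 42 °C (across genes, which are not independent replicates). Medians went from 0.95 in the 181 genes at or under a log2 CPM of 0 to -0.72 in the 75 genes above 10. The 181 genes had median CPM of only 0.634 in total and 1.12 in new RNA at 37 °C. Genes that low in total RNA can pass the count filter through high values in another group, so their 0.95 decides nothing. From the 942 genes with a log2 CPM of 2 to 4 upward, the median still fell from 0.12 to -0.72. With abundance and change taken from different total RNA libraries the correlation was -0.358, among the 296 genes with a log2 CPM of at least 8 it was -0.334, and with length offsets it was -0.466. These argue against shared counting noise, an even background and a length trend as the whole cause. No biological explanation was tested.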
